A study of Homo sapiens with 4 samples.

How the data were processed

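Bulk RNA was measured in 4 human libraries from xenografts of 16D CRPC, a castration-resistant prostate cancer line derived from LNCaP cells. Per the labels, 2 libraries came from cells over-expressing LASP1 (LASP1-OE) and 2 from mock-transduced cells (MOCK), numbered as biological replicates 1 and 2 within each group. Per the labels' protocols, ribosomal RNA was depleted from total RNA and strand-specific libraries were read as paired ends on a DNBSEQ-G50 instrument. The labels name no batch and do not say whether the 2 replicates of a group came from separate animals, so the p-values measure the spread between these samples, which may in part be technical.

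The deposited values are whole-number counts of reads per Ensembl gene, which the authors did not normalise. Per the submitters' processing notes, STAR 2.6.0a and HTSeq 0.11.2 were used with the human genome build GRCh38. The annotation release, the strand setting of the counting step and any removal of mouse reads are not given in the sources used here. Antisense genes and genes that overlap or share sequence with a paralog (histone, UGT2B, HLA and ribosomal protein genes among those named) therefore carry uncertain counts. Reads at LASP1 can come from the native gene and from the introduced copy, and the counts do not separate them.

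The file lists 58243 genes. Biotypes, coordinates (GRCh38), exonic lengths and GC contents were taken from GENCODE release 29, which held 57980 of these identifiers. A current symbol was found for 57532 identifiers, and 263 identifiers had a symbol in neither source. Of 781 list genes, 779 were matched. The 2 histone genes H3C2 and H3C3 were not. Total counts ranged from 18929978 to 19582053 per library. The counting intervals and floors given below cover counting error only.

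Genes with low counts were removed with edgeR's filterByExpr at its defaults (minimum count 10, minimum total count 15), which left 17755 genes. LASP1-OE was tested against MOCK in all 4 libraries with edgeR 4.0.16 in R 4.3.3, using TMM factors, the quasi-likelihood F-test with the group as the only term, and two-sided p-values with Benjamini-Hochberg adjustment; a gene was called at an adjusted p under 0.05. The fit had 2 residual degrees of freedom per gene and 8.61 prior degrees of freedom, and the common dispersion was 0.0179, a biological coefficient of variation of 13.4%. Expression levels are in CPM, edgeR's counts scaled by TMM-adjusted library size, given as mean ± SD with n = 2 per group. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic and is approximate. Where a group had 0 counts in both libraries, the fold was set against a floor of 3 counts over the group; where it had 1 to 3 counts, the ratio is given with a 95% exact binomial counting interval.

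A set of 29 gene lists and the rule for the named genes were fixed before the data were examined. Lists with at least 5 tested genes (25 of the 29) were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The named genes were the tested members of the study axis list, the 8 largest rises and 8 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups, up to 4 members of each other list with the smallest adjusted p, and 13 prostate cancer marker genes. Genes outside this rule were chosen after their values were seen. In the results these are ACTA1, ALDOC, CCNE2, COL6A1, DLL3, INSIG2, KDM3A, MALAT1, MYH7, NPPA, ONECUT2, SC5D and STEAP2.

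The steps were tested on simulated data: counts for the real genes, from the means and library sizes of these libraries, with known genes changed. Of the changed genes that passed the filter (17544 genes tested), edgeR recovered 96.9% at a fold of 4, 74.6% at a fold of 2 and 17.9% at a fold of 1.5, and called 2 of 17293 unchanged genes. Every simulated gene had the common dispersion, no GC trend was simulated and most genes were left unchanged. In the real data 7314 of 17755 genes were called. The simulated recovery and false calls therefore show that the steps run correctly and do not give the rates in the real data. In the same simulation camera with the preset correlation called 2 of 2 lists of 30 genes moved by a fold of 1.5 and 0 of 18 unmoved lists. With an estimated correlation it called 0 of the 2 moved lists. The simulated genes were drawn independently of each other, so these counts do not cover lists whose genes vary together. The alternatives tried were other scaling factors (RLE, library size alone), no filter, a filter at 1 CPM, DESeq2 1.42.0, limma-voom, the replicate number as a block, each library left out, a log2 fold change of at least 1, and removal of 4 highly counted genes. For the lists they were an estimated correlation, a prior count of 0.5, voom values and fry. After the data were seen, 3 alternatives were added for the counts: removal of each library's trend with GC content, protein-coding genes only, and the replicate numbers crossed between groups. Levels of genes on the Y chromosome and of the X-inactivation locus are not reported.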

Results

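The series profiled RNA from xenograft tumours of the castration-resistant prostate cancer line 16D CRPC, and the single comparison its design implies asks which transcripts differ between tumours over-expressing LASP1 and mock-transduced tumours. LASP1 is an actin-binding adaptor protein, and the series title places it in an axis with the chemokine receptor CXCR4, the histone methyltransferase G9a (EHMT2), SNAIL (SNAI1) and the neuronal-gene repressor REST. There were 2 LASP1-OE and 2 MOCK libraries. Total counts were 18929978 and 19582053 in LASP1-OE replicates 1 and 2 and 19388209 and 18991563 in MOCK replicates 1 and 2. Levels below are CPM (mean ± SD, n = 2 per group), and changes are given for LASP1-OE relative to MOCK. All adjusted p-values for genes come from edgeR's two-sided quasi-likelihood test and those for lists from limma's camera test. Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom of 27.0 for the LASP1-OE pair and 16.9 for the MOCK pair. This does not show whether they are independent samples.

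LASP1 (chromosome 17, 38869859 to 38921770 in GRCh38) was counted at 1238 and 1392 CPM in the 2 LASP1-OE libraries and at 100.3 and 96.9 CPM in the 2 MOCK libraries, a 13.3-fold difference (log2 fold change 3.74 ± 0.14 SE, adjusted p = 4.34e-08). REST (chromosome 4, 56907876 to 56966678) stood at 93.7 ± 3.77 CPM against 101.6 ± 6.28 CPM and was not called (log2 fold change −0.12 ± 0.14, adjusted p = 0.527). SNAI1, the SNAIL transcription factor, stood at 4.45 ± 0.473 against 5.65 ± 0.129 CPM (−0.34 ± 0.23, adjusted p = 0.254), and EHMT2 at 110.7 ± 9.46 against 114.3 ± 10.7 CPM (−0.05 ± 0.14, adjusted p = 0.823), neither passing the test. CXCR4 had 5 and 9 counts in LASP1-OE and 3 and 10 in MOCK, too few to be tested at this depth.

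Among the other axis genes, ACKR3, the second receptor for CXCL12, rose from 102.1 ± 19.2 to 183.2 ± 2.14 CPM (log2 fold change 0.84 ± 0.16, adjusted p = 0.00174). The ligand CXCL12 was called higher (3.41 ± 0.75, adjusted p = 0.00419), but its counts were 19 and 99 in the LASP1-OE libraries against 5 and 5 in MOCK. Its log2 fold change was 1.84 without LASP1-OE replicate 2 and 4.13 without LASP1-OE replicate 1. The corepressor and methyltransferase genes EHMT1 (log2 fold change −0.50), HDAC2 (−0.56) and KDM1A (−0.49) fell (adjusted p = 0.0139, 0.0175 and 0.0181). These 3 calls, not their direction, were lost without LASP1-OE replicate 2 (−0.54, −0.46 and −0.44, adjusted p = 0.0697, 0.144 and 0.134) and with the replicate block. Without LASP1-OE replicate 1 only HDAC2 of the 3 was called, without MOCK replicate 2 only EHMT1, and without MOCK replicate 1 the EHMT1 call was lost (adjusted p = 0.0941). HDAC1 (−0.22, adjusted p = 0.226; called with GC trends removed, adjusted p = 0.0122) and RCOR1 (0.15, adjusted p = 0.438) were not called. Of the 11 tested axis genes 3 were higher and 3 lower, also when adjusted over the list alone, and the list was not called (camera adjusted p = 0.892). Its median was −0.12 and its mean 0.53, so the 2 differ in sign. This list names the study's own axis and includes the over-expressed gene, so its counts are not independent evidence.

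**Figure D1:**
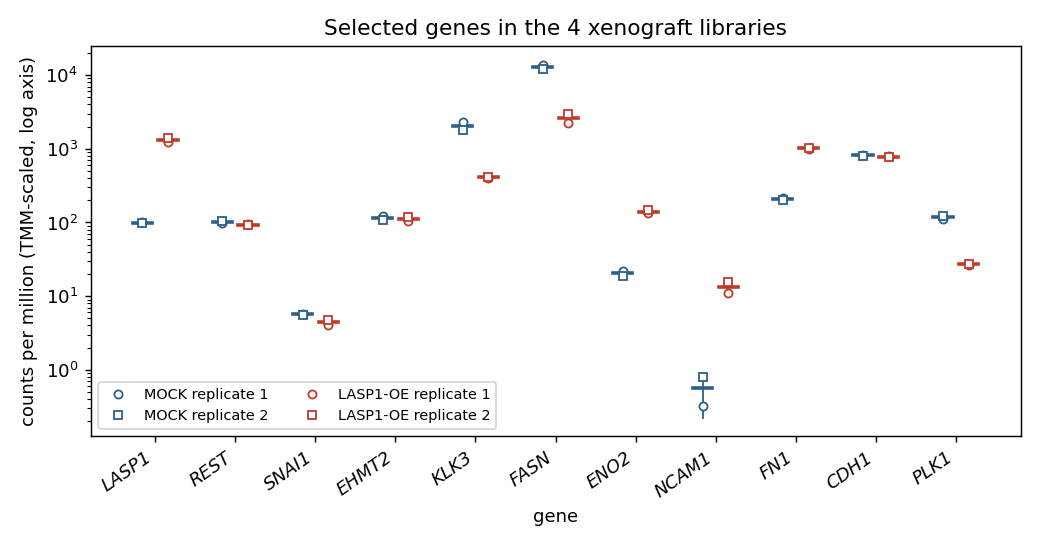
Each point is 1 library's level of a gene in TMM-scaled CPM on a log axis, with a horizontal line at the group mean and a vertical line of 1 SD on each side (n = 2). LASP1 was 13.3-fold and ENO2 6.91-fold higher in LASP1-OE, KLK3 4.93-fold and PLK1 4.32-fold lower, and REST, SNAI1, EHMT2 and CDH1 did not pass the test.

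The tumours differed in a large part of the transcriptome. The 8 protein-coding genes named for their rise included FAM135B (63.3 ± 0.984 CPM in LASP1-OE, with 3 counts in all over the MOCK libraries; ratio 784, 95% counting interval 268 to 3806), the matrix glycoprotein gene TNC (108.7 ± 6.38 against 0.270 ± 0.305 CPM, log2 fold change 8.62 ± 0.35), the pregnancy-associated metalloproteinase gene PAPPA (8.06 ± 0.28) and NR3C1, which encodes the glucocorticoid receptor (48.8 ± 5.31 against 0.189 ± 0.267 CPM, 7.97 ± 0.44). BHLHE22 (8.15), the protease gene TLL1 (7.90) and the synaptic adhesion gene LRRTM3 (7.81) also rose, as did PLSCR5, with a ratio of 326 (counting interval 90.0 to 2701). All 8 had adjusted p-values of 1.28e-06 or less in edgeR's test. The few MOCK counts of these genes lay mostly in MOCK replicate 2 (0 and 3 for FAM135B, 0 and 2 for PLSCR5, 1 and 9 for TNC, 0 and 7 for NR3C1, 1 and 32 for TLL1). The ratios of FAM135B and PLSCR5 thus rest on that library alone. Without MOCK replicate 1 the log2 fold changes were 7.77 for TNC, 6.98 for NR3C1, 7.17 for BHLHE22, 6.93 for TLL1 and 7.04 for LRRTM3. Without MOCK replicate 2 those of TNC, TLL1 and LRRTM3 were 10.79, 11.76 and 9.48, on 1 MOCK count each. NR3C1 and BHLHE22 then had 0 MOCK counts.

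On the other side, the sialyltransferase gene ST6GALNAC1 had 1 count in all in LASP1-OE and 108.5 ± 3.69 CPM in MOCK, a ratio of 4305 (counting interval 772 to 170094), and RALYL had 3 counts against 218.5 ± 0.574 CPM (ratio 2891, counting interval 989 to 14019). KCNMA1, a calcium-activated potassium channel gene, fell from 433.1 ± 3.79 to 0.931 ± 0.0642 CPM (log2 fold change −8.85 ± 0.21, adjusted p = 4.30e-09). The prostaglandin receptor gene PTGFR (−9.67) and the fatty acid elongase gene ELOVL2 (−9.27; −8.61 without LASP1-OE replicate 1 and −10.71 without LASP1-OE replicate 2) fell to 0.151 and 0.148 CPM. SLC38A4 and DOCK8 had 0 counts in both LASP1-OE libraries and were at least 81.1-fold and at least 79.4-fold lower. UGT2B28 had 1 count in all in LASP1-OE (ratio 1082, counting interval 194 to 42797), with the reservation that UGT2B genes share sequence.

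Of 17755 genes tested, 7314 were called by edgeR, 3817 higher and 3497 lower, and 3920 of them differed by at least 1 on the log2 scale (2421 higher and 1499 lower). Protein-coding genes made up 5925 of the calls (2770 higher, 3155 lower). Long intergenic non-coding RNAs moved mostly upward, with 270 higher and 81 lower of 961 tested, and antisense genes had 250 higher and 92 lower of 1091, the latter subject to the unknown strand setting. The nuclear RNA MALAT1 took 36508 ± 6313 CPM in LASP1-OE and 20190 ± 888 in MOCK (edgeR adjusted p = 0.000168). Without LASP1-OE replicate 2 the count of called genes was 4815.

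Several neuroendocrine markers were higher in the LASP1-OE tumours. NTS, the neurotensin gene, rose from 0.405 ± 0.572 to 63.5 ± 15.7 CPM (log2 fold change 7.27 ± 0.51), NCAM1, the CD56 adhesion molecule, from 0.566 ± 0.345 to 13.2 ± 3.03 CPM (4.54 ± 0.37), DDC, the aromatic amino acid decarboxylase, from 4.11 ± 1.47 to 76.4 ± 3.97 CPM (4.21 ± 0.23), SYT4 by 3.08 ± 0.16 and the neuron-specific enolase gene ENO2 by 2.79 ± 0.16 (adjusted p at most 5.44e-06, edgeR). Of 13 tested markers 9 were higher and 2 lower (10 and 2 adjusted over the list alone). The 2 lower ones, named after their values were seen, were ONECUT2 (−1.03) and DLL3 (−0.65). The list was called higher (median 1.67, camera adjusted p = 0.00112; adjusted p = 0.308 with an estimated correlation). SYP, the synaptophysin gene, was at 4.30 ± 0.551 against 2.91 ± 0.0640 CPM and did not pass (0.56 ± 0.25, adjusted p = 0.0924), but did with GC trends removed (adjusted p = 0.0322). CHGA (1, 0, 0 and 0 counts) and FOXA2 (0, 0, 0 and 1; LASP1-OE first) were too low to be tested. The list holds 32 markers. With library size alone, the replicate block or protein-coding genes only, 9 were higher and 1 lower. Without MOCK replicate 1 the counts were 10 higher and 1 lower and the log2 fold change of NTS, which had 0 and 15 MOCK counts, was 6.27. Without MOCK replicate 2 that of NCAM1 was 5.30.

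Neuronal genes that REST is known to repress went both ways. DPYSL3 (1.65 ± 0.25), RUNDC3A (2.23 ± 0.36) and the presynaptic scaffold gene BSN (1.04 ± 0.17) rose, and the calcium channel gene CACNA1H fell (−2.20 ± 0.19), with adjusted p-values at most 0.000751. In total 9 of 21 were higher, 3 lower and 9 not called (the same counts adjusted over the list alone), with a median of 0.43, and the list was not called (camera adjusted p = 0.0641). Without LASP1-OE replicate 2 the counts were 5 higher and 1 lower, without MOCK replicate 1 they were 8 and 1, and the list was called without LASP1-OE replicate 1 (adjusted p = 0.0492) and with GC trends removed (adjusted p = 0.0281). One of the risers, the natriuretic peptide gene NPPA (2.63), is also a heart-muscle gene and had 50 counts in LASP1-OE replicate 2 against 18 in LASP1-OE replicate 1 and 3 and 7 in the MOCK libraries. Axon guidance and synaptic adhesion genes split too, 16 higher and 8 lower of 29 (17 and 8 adjusted over the list alone; camera adjusted p = 0.175). Fry, which tests the list by itself, called it upward (adjusted p = 0.0350). The neurexin gene NRXN3 fell from 69.6 ± 8.51 to 5.74 ± 0.307 CPM and the ephrin receptor genes EPHA3 (−4.70) and EPHA7 (−6.65) fell, all with adjusted p-values at most 2.46e-07.

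**Figure D2:**
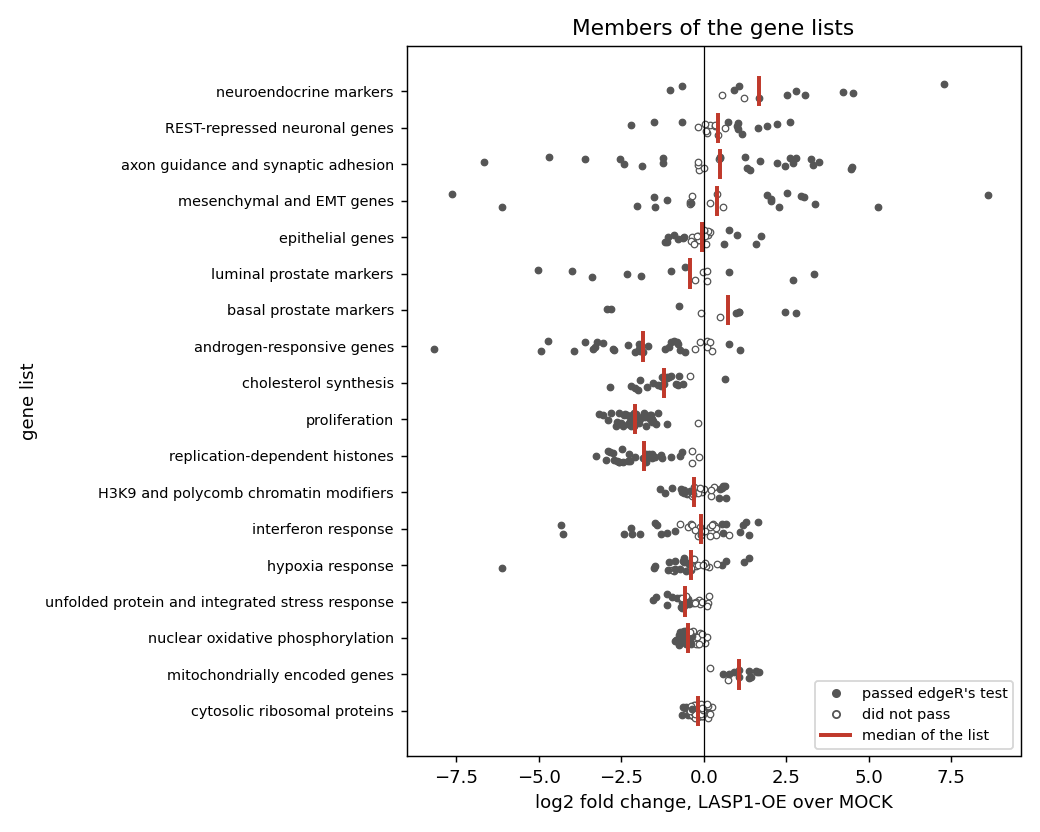
Each point is the fitted log2 fold change of 1 list member in LASP1-OE over MOCK (filled where it passed edgeR's test at an adjusted p under 0.05), and the red line is the list's median; vertical scatter within a list carries no meaning. The medians were −2.09 for proliferation, −1.84 for androgen-responsive genes and 1.67 for neuroendocrine markers, and the mesenchymal list spread to both sides of 0.

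Androgen-responsive genes were mostly lower in LASP1-OE. KLK3 (chromosome 19, 50854915 to 50860764), which encodes prostate-specific antigen, fell from 2037 ± 356 to 413.6 ± 8.62 CPM (log2 fold change −2.30 ± 0.15, adjusted p = 1.15e-06), the prostein gene SLC45A3 from 1533 ± 277 to 50.4 ± 11.4 CPM (−4.93 ± 0.21), and MAF (−4.71), ADAMTS1 (−3.92) and CHRNA2 (−8.16) also fell (adjusted p at most 7.73e-08). TMPRSS2 stood at 460.1 ± 45.7 against 551.2 ± 119.3 CPM and was not called (−0.26 ± 0.16, adjusted p = 0.231), although it was without MOCK replicate 2 (−0.50, adjusted p = 0.0349). Of 35 tested genes of the list 27 were lower, 2 higher (among them STEAP2, 0.78, named after its value was seen) and 6 not called, also when adjusted over the list alone. The list was called lower (median −1.84, camera adjusted p = 2.41e-10; adjusted p = 0.308 with an estimated correlation).

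Luminal prostate markers did not move together. ACP3, the prostatic acid phosphatase gene, rose from 27.2 ± 1.87 to 276.4 ± 24.6 CPM and AMACR from 24.7 ± 6.06 to 163.2 ± 11.7 CPM, while the fatty acid synthase gene FASN fell from 12912 ± 1395 to 2596 ± 507 CPM and AZGP1 from 42.0 ± 6.59 to 4.02 ± 0.742 CPM (edgeR adjusted p at most 1.78e-06). In all 3 of 14 were higher and 7 lower, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.129). It was called lower with the replicate block (adjusted p = 0.0295). Basal markers had 4 higher and 3 lower of 10 (6 and 3 adjusted over the list alone; camera adjusted p = 0.516), with ITGB4 (2.46 ± 0.26) and COL17A1 (2.81 ± 0.47) higher and LAMA3 (−2.92 ± 0.39) and EGFR (−0.74 ± 0.13) lower.

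Genes linked to epithelial-mesenchymal transition changed in both directions. WNT5A, a secreted Wnt ligand, rose from 15.2 ± 3.56 to 589.0 ± 24.9 CPM (log2 fold change 5.27 ± 0.20, adjusted p = 3.97e-08), fibronectin (FN1) from 210.1 ± 9.63 to 1020 ± 20.5 CPM (2.28 ± 0.13, adjusted p = 5.54e-07) and TNC as above. SNAI2, the SLUG transcription factor, fell to 2 counts in all from 11.2 ± 1.06 CPM (ratio 222, counting interval 60.9 to 1835), and the intermediate filament gene VIM fell from 9.79 ± 0.878 to 4.54 ± 2.14 CPM (−1.10 ± 0.30, adjusted p = 0.0127), a call lost without LASP1-OE replicate 1 (−0.70, adjusted p = 0.0983), with a log2 fold change of −1.71 without LASP1-OE replicate 2. CDH2, the N-cadherin gene, was called higher (3.38 ± 0.65, adjusted p = 0.00204) on 33 and 127 counts against 4 and 10. Its log2 fold change was 2.16 without LASP1-OE replicate 2, 4.01 without LASP1-OE replicate 1 and 4.14 without MOCK replicate 2. CDH1, the E-cadherin gene, stood at 784.2 ± 24.2 against 811.5 ± 21.5 CPM (−0.05 ± 0.12, adjusted p = 0.776). Of 23 tested mesenchymal genes 10 were higher and 7 lower (11 and 7 adjusted over the list alone), and the list was not called (camera adjusted p = 0.465). The 7 lower genes became 3 without LASP1-OE replicate 1 and 4 without LASP1-OE replicate 2, without MOCK replicate 1 or with DESeq2. Heart-muscle transcripts were counted most in LASP1-OE replicate 2, where MYH7 had 5498 counts against 1219 in LASP1-OE replicate 1 and 123 and 393 in the MOCK libraries, and CDH2 and CXCL12 had the same order of LASP1-OE libraries.

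Epithelial genes were 5 higher, 7 lower and 20 not called of 32, also adjusted over the list alone (camera adjusted p = 0.419). The tight junction gene OCLN (1.60 ± 0.15) and OVOL1 (1.75 ± 0.23) rose, and the splicing regulator gene ESRP2 (−1.07 ± 0.15) and CLDN7 (−1.18 ± 0.17) fell. The 5 higher and 7 lower became 5 and 4 without LASP1-OE replicate 1 and 3 and 6 without LASP1-OE replicate 2, and 12 were lower with GC trends removed. Actin and focal adhesion partners of LASP1 were 5 higher and 5 lower of 20, also adjusted over the list alone (camera adjusted p = 0.840), with PFN1 (−1.03), CFL1 (−0.94) and ACTB (−0.55) lower and LIMA1 (0.76) higher. These counts became 3 and 3 without LASP1-OE replicate 1 or without MOCK replicate 2, 2 and 4 without LASP1-OE replicate 2, 3 and 5 without MOCK replicate 1, and 2 and 3 with the replicate block, with the LIMA1 call lost without LASP1-OE replicate 1 or MOCK replicate 1. TGF-beta targets were 6 higher and 4 lower of 16 (6 and 5 adjusted over the list alone; camera adjusted p = 0.771), with BAMBI (1.75) higher and PMEPA1 (−1.94), ID2 (−1.40) and SMAD6 (−0.87) lower, and 3 higher and 3 lower without LASP1-OE replicate 2. The TGF-beta list's median (−0.20) and mean (0.22) differ in sign, and for the actin list the median (0.01) and mean (0.06) lay above 0 while camera ranked it downward.

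Cell cycle genes were lower in the LASP1-OE tumours almost without exception. MYBL2 fell from 108.8 ± 5.48 to 14.5 ± 0.868 CPM, thymidine kinase (TK1) from 132.6 ± 6.37 to 15.9 ± 2.48 CPM, the mitotic transcription factor gene FOXM1 from 236.8 ± 30.1 to 45.4 ± 2.97 CPM and the kinase gene PLK1 from 117.0 ± 5.59 to 27.1 ± 0.574 CPM (log2 fold changes −2.91, −3.06, −2.38 and −2.11, adjusted p at most 1.60e-06). Of 40 proliferation genes 39 were lower and 0 higher, also adjusted over the list alone. The exception was CCNE2 (−0.18, not called). The list was called lower (median −2.09, camera adjusted p = 7.96e-19; adjusted p = 0.515 with an estimated correlation). Replication-dependent histone genes had 31 lower and 0 higher of 34 (32 lower adjusted over the list alone), with H1-5 at 12.9 ± 0.691 against 124.7 ± 3.98 CPM, and H2AC11 (−2.30), H2BC17 (−2.64) and H3C10 (−2.07) also lower. That list was called lower too (median −1.81, camera adjusted p = 2.55e-17; adjusted p = 0.308 with an estimated correlation).

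Chromatin modifiers of the H3K9 and polycomb systems were 6 higher and 9 lower of 27, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.283). SUV39H1 fell to 7.97 ± 0.152 CPM (log2 fold change −1.33 ± 0.18), EZH2, the polycomb methyltransferase gene, from 39.8 ± 5.53 to 17.7 ± 3.20 CPM (−1.17 ± 0.19) and DNMT1, the maintenance DNA methyltransferase gene, fell by 0.97 on the log2 scale (adjusted p at most 0.000663). CBX5 fell by 0.69 on the log2 scale (adjusted p = 0.00250), a call lost without LASP1-OE replicate 2. The 6 higher and 9 lower genes became 1 and 5 without LASP1-OE replicate 1, 5 and 4 without LASP1-OE replicate 2, 3 and 6 without MOCK replicate 1, and 9 and 15 with GC trends removed.

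Sterol synthesis genes fell as a group. INSIG1, a sterol sensor, fell from 508.7 ± 16.8 to 111.5 ± 3.63 CPM, the farnesyl diphosphate synthase gene FDPS from 259.6 ± 4.12 to 61.5 ± 2.19 CPM and squalene synthase (FDFT1) from 573.5 ± 15.7 to 145.6 ± 0.202 CPM (log2 fold changes −2.19, −2.08 and −1.98, adjusted p at most 1.78e-06). Of 22 tested genes 20 were lower and 1, SC5D (0.63), was higher (21 and 1 adjusted over the list alone). The SC5D call was lost without LASP1-OE replicate 1, without MOCK replicate 1, with no filter and with the replicate block. The list was called lower (median −1.21, camera adjusted p = 8.21e-09; adjusted p = 0.308 with an estimated correlation).

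Nuclear and mitochondrial genes of oxidative phosphorylation went opposite ways. Of 47 nuclear subunit genes 29 were lower and 0 higher (31 lower adjusted over the list alone), by small amounts, such as NDUFB10 (−0.83 ± 0.14), COX5A (−0.74 ± 0.14) and ATP5MC1 (−0.73 ± 0.14). The list was called lower (median −0.46, camera adjusted p = 3.97e-06; adjusted p = 0.308 with an estimated correlation). The 29 became 10, 14 and 17 without LASP1-OE replicate 1, LASP1-OE replicate 2 and MOCK replicate 1, 14 with the replicate block and 18 with library size alone. Of the 13 mitochondrially encoded genes 11 were higher (12 adjusted over the list alone), among them MT-ND3 (1.67 ± 0.36), MT-ND1 (1.43 ± 0.34), MT-ND2 (1.63 ± 0.39) and MT-ND5 (1.39 ± 0.34), and the list was called higher (median 1.08, camera adjusted p = 0.0467, or 0.796 with an estimated correlation). Their summed level was 54730 and 27853 CPM in the LASP1-OE libraries against 23472 and 23812 CPM in MOCK, so that without LASP1-OE replicate 1 only 2 of the 13 were called and the list was not (adjusted p = 0.189). The log2 fold changes without that library were 0.75 for MT-ND3, 0.52 for MT-ND1, 0.53 for MT-ND2 and 0.47 for MT-ND5. That of MT-ND2 was 2.23 without LASP1-OE replicate 2. Mitochondrial ribosomal RNA also differed between the replicates of both groups, at 8.22 and 1573 CPM in LASP1-OE and 149.3 and 6.52 CPM in MOCK. With DESeq2 1 of the 13 genes was called, and none of the 4 named (adjusted p = 0.0538 to 0.123), and with no filter 4 were. The list was also lost without MOCK replicate 1 (adjusted p = 0.0914), with library size alone (0.0650), GC trends removed (0.0695), a prior count of 0.5 (0.0533) and fry (0.358).

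Stress and hypoxia genes tended downward. Of 26 genes of the unfolded protein and integrated stress responses 15 were lower and 0 higher, also adjusted over the list alone, with the pseudokinase gene TRIB3 (−1.54 ± 0.24), the serine synthesis gene PSAT1 (−0.97 ± 0.16), SDF2L1 (−1.11 ± 0.21) and MANF (−0.80 ± 0.16) among them. That list was called lower (median −0.56, camera adjusted p = 0.00183; adjusted p = 0.308 with an estimated correlation), and 6 genes were lower without LASP1-OE replicate 2. Of 32 hypoxia genes 15 were lower and 4 higher (17 and 5 adjusted over the list alone), and the list was called lower (median −0.39, camera adjusted p = 0.00747; adjusted p = 0.481 with an estimated correlation). Hexokinase 2 (HK2, −1.47 ± 0.15) and NDRG1 (−1.05 ± 0.14) fell, LOX fell to 2 counts in all (ratio 77.4, counting interval 21.0 to 645) and BNIP3L rose (1.37 ± 0.14). The 4 higher genes, named after their values were seen apart from BNIP3L, also included INSIG2, KDM3A and ALDOC. Ribosomal protein genes had 7 lower and 0 higher of 74 (0 lower adjusted over the list alone), led by RPS2 (−0.58), RPS16 (−0.63), RPL34 (−0.55) and RPLP2 (−0.64). Camera called that list lower (median −0.16, adjusted p = 0.0224; adjusted p = 0.796 with an estimated correlation), but without LASP1-OE replicate 1 no gene of it was called and the list was not (adjusted p = 0.0679), and it was not called without MOCK replicate 1 (adjusted p = 0.173), where 1 gene was lower. The list was also lost with library size alone (adjusted p = 0.0752), the replicate block (0.190) and fry (0.211). The 7 lower genes became 4 without LASP1-OE replicate 2, 16 without MOCK replicate 2, 3 with the replicate block, 11 with DESeq2 and 27 with GC trends removed. With library size alone 5 were lower and 1 higher.

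Immediate early, interferon and NF-kB genes were mixed. FOS rose from 3.82 ± 0.593 to 32.0 ± 1.91 CPM (log2 fold change 3.07 ± 0.20), EGR1 by 3.15 ± 0.31 (3.76 without MOCK replicate 2) and FOSB by 2.43 ± 0.28, while the heat shock gene HSPB1 fell by 1.41 on the log2 scale (adjusted p at most 7.65e-05). Of 21 genes of that list 6 were higher and 5 lower (6 and 6 adjusted over the list alone; camera adjusted p = 0.840), and its median (−0.08) and mean (0.28) differ in sign. Interferon response genes were 8 higher and 11 lower of 37, also adjusted over the list alone (camera adjusted p = 0.283), with HERC5 (−4.32 ± 0.32), OAS3 (−2.17 ± 0.18), HERC6 (−1.93 ± 0.18) and DDX60 (−2.19 ± 0.31) lower. The 8 higher genes became 3 without LASP1-OE replicate 2, 4 without MOCK replicate 2 or with no filter, and 5 with DESeq2. NF-kB targets were 3 higher and 1 lower of 9 (4 and 1 adjusted over the list alone; camera adjusted p = 0.549), namely TNFAIP2 (1.85), BIRC3 (from 1.75 ± 0.730 to 4.96 ± 0.727 CPM), CD83 (0.59) and NFKBIA (−1.09). The CD83 call (adjusted p = 0.0478) was lost when any single library was left out.

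Markers of other cell types were few and mixed. Fibroblast markers were 4 higher and 1 lower of 8 (5 and 1 adjusted over the list alone; camera adjusted p = 0.283), namely COL5A1 (2.88 ± 0.26), COL6A2 (1.23 ± 0.18), COL6A1 (1.09, named after its value was seen) and COL3A1 (53 counts against 2, ratio 24.8, counting interval 6.54 to 210.3) above and FBLN1 (−1.64 ± 0.24) below. Skeletal muscle markers were 4 higher and 1 lower of 6, also adjusted over the list alone (camera adjusted p = 0.438), namely NEB (1.61), TTN (2.16), CKM (2.73) and ACTA1 (1.51, named after its value was seen) above and ATP2A1 (−0.91) below. Without LASP1-OE replicate 2 only NEB of these was called, with log2 fold changes of 0.83 for TTN and 1.59 for CKM. Without LASP1-OE replicate 1 those 2 were 2.84 and 3.34, and without MOCK replicate 2 that of CKM was 3.42 and the counts were 3 higher and 2 lower. With DESeq2 2 were higher and 0 lower, with a filter at 1 CPM 2 and 1, and with GC trends removed 4 and 2. Too few genes for a list test were counted among endothelial markers (4 tested, with FLT1 at 2.66 and ESAM at 0.71 higher and VWF at −2.22 lower, and 3 higher and 1 lower adjusted over the list alone), adipocyte markers (3 tested, GPD1 at 1.54 higher and PLIN4 at −1.15 lower, also adjusted over the list alone) and erythroid markers (SLC4A1 at 2.46, from 9 counts in MOCK). The calls of FLT1, ESAM, GPD1 and PLIN4 were lost without LASP1-OE replicate 2 and without MOCK replicate 1, that of PLIN4 also without LASP1-OE replicate 1, and that of ESAM when any single library was left out. FLT1 had 0 and 5 MOCK counts. Without MOCK replicate 1 the log2 fold change of FLT1 was 1.67 and that of PLIN4 −0.48. EGFL7 (0.59) was not called, but was without LASP1-OE replicate 1 or MOCK replicate 1 (adjusted p = 0.0425 and 0.000289), with library size alone, with the replicate block and with GC trends removed. With DESeq2 the calls of FLT1, ESAM and GPD1 were lost, and with limma-voom or no filter those of ESAM and PLIN4. None of the 16 macrophage and leukocyte markers passed the filter. Reads were counted with the human genome build, so the marker counts do not show how many mouse host cells the tumours held.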

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

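The alternatives with GC trends removed, protein-coding genes only or crossed replicate numbers, and the list counts without single libraries, were added after the data were seen. Of 7314 genes called, 0 were called in the opposite direction under any alternative for the genes. Requiring an absolute log2 fold change of at least 1 left 3920 genes, by construction. Leaving out 1 library gave 4815 (without LASP1-OE replicate 2) to 6234 (without MOCK replicate 1) genes, with fewer samples, and assumes that the lone sample varies like the others. Other factors, filters and tools gave 6277 (DESeq2) to 7350 (RLE factors) genes, removal of GC trends 9976, protein-coding genes only 5737, and the replicate block 5541. The labels do not tie the replicates of the 2 groups together beyond a shared number, and crossing the numbers gave 10872. With library size alone the median log2 fold change of the tested genes was 0.11 in place of 0.02, and 60.6% of the called genes were higher in place of 52.2%. The share was 45.6% with DESeq2, 47.7% with GC trends removed and 49.1% with no filter. In the remaining alternatives it lay between 50.1% (crossed numbers) and 55.5% (replicate block). The log2 fold change of LASP1 ranged from 3.64 to 3.83 and was called under all 14 alternatives run for it. The 137 named genes gave 1844 comparisons on the same side of the threshold, 63 in which a call was lost (22 genes) and 8 in which one was gained (4 genes). There were 0 reversals among genes called in at least 1 of the 2 fits compared. Genes called in neither fit counted as the same whatever their sign, such as CDH1, whose log2 fold change ran from −0.118 to 0.040 over its 14 alternatives. With an estimated correlation 0 of the 25 lists were called, against 10. The 2 simulated lists of 30 genes moved by a fold of 1.5 were not called either. Larger moves were not simulated. The simulated genes were drawn independently, while estimated correlations ran from −0.0254 (neuroendocrine markers) to 0.965 (mitochondrially encoded genes) over the 10 called lists. The simulation thus cannot decide which setting is right for lists whose genes vary together. The study axis list was ranked downward by camera and upward by fry (adjusted p = 0.0235), which tests a different question, namely whether its own genes move 1 way; its alternatives ranged from 0.0235 to 0.974. Replicate 1 minus replicate 2 differences followed GC content (correlation −0.73 in LASP1-OE, 0.65 in MOCK, over 11105 protein-coding genes above 5 CPM). These differences correlated between the groups at −0.54, and at −0.13 after removal of GC trends. Same-numbered libraries thus deviated in opposite ways, which goes with more calls after GC removal or crossing and fewer with the replicate block. What produced the GC trends, and the causes of the other shifts, were not tested. Depth limits genes such as CXCR4, CHGA and FOXA2, whose counts were too low to test.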

Other observations

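The tests of heart-muscle reads and of chromosome 4 copies were chosen only after the result was seen, as were the receptor, glucuronosyltransferase and surface-protein genes and the other genes named with them. The tests of GC content, of strongly changed genes, of trends with length and of androgen-repressed genes were set down before their results.

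Steroid receptor genes moved in both directions in the LASP1-OE tumours. Beside NR3C1, the progesterone receptor gene PGR rose from 0.566 ± 0.269 to 20.7 ± 0.308 CPM (log2 fold change 5.18 ± 0.30, edgeR adjusted p = 5.54e-07), while the mineralocorticoid receptor gene NR3C2 fell from 57.8 ± 2.90 to 9.37 ± 0.282 CPM (−2.63 ± 0.17, adjusted p = 1.11e-06). The glucuronosyltransferase genes UGT2B11 (−8.53), UGT2B15 (−4.88) and UGT2B17 (−2.92), which share sequence with each other and so carry uncertain counts, fell. UGT2B15 and UGT2B17 encode enzymes that clear androgens. PGR had 7 and 14 MOCK counts, and UGT2B11 had 14 and 6 counts in the LASP1-OE libraries, so their folds depend on the library. The desaturase gene SCD fell from 3627 ± 351 to 1154 ± 37.0 CPM.

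Genes for cell-surface proteins that are drug or imaging targets moved apart. CD274, which encodes PD-L1, rose from 0.485 ± 0.535 to 34.2 ± 3.14 CPM (6.12 ± 0.41, adjusted p = 1.60e-06), and MET (3.20), MME (1.83), NECTIN4 (1.32), STEAP2 (0.78) and FOLH1, the PSMA gene (0.75), also rose. CD276 (−0.73), ERBB2 (−0.58) and DLL3 (−0.65) fell, and STEAP1 was not called (0.09, adjusted p = 0.657). The odorant receptor gene OR51E2 rose from 0.135 ± 0.115 to 13.8 ± 1.01 CPM, and the long non-coding RNAs COLCA1 (2.46) and CRNDE (1.65) rose as well. The MOCK counts in replicates 1 and 2 were 2 and 16 for CD274 (0.107 and 0.863 CPM), 1 and 4 for OR51E2 and 4 and 8 for MET, so the sizes of these rises depend on which MOCK library is used.

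Of 20 heart-muscle genes, 18 had a ratio between LASP1-OE replicate 2 and replicate 1 within 1.5 times of their median ratio of 4.42, and their summed level was 253.4 and 1058 CPM in LASP1-OE against 63.0 and 121.6 CPM in MOCK (TTN at 358.6, MYH7 at 268.4 and ACTC1 at 122.4 CPM in LASP1-OE replicate 2). Fast skeletal muscle genes had a median count of 0 there, which argues against fast skeletal muscle of the mouse host. Slow or heart muscle of the host was not tested. TNC, WNT5A, FN1 and CALD1 were at most 1.09 times higher in LASP1-OE replicate 2, which argues against heart-muscle reads as the source of their rises. Reads of human heart-muscle-like cells, or of another library, may have been carried in, but between the MOCK libraries 11 of the 20 lay within 1.5 times of their median ratio of 2.00 (range 0.431 to 3.69), so 1 source with a fixed ratio over the 4 libraries is not shown. For CDH2, CXCL12, MYL9 and CCN2 all 4 genes varied against the markers within the range that the markers showed, but so did FN1, so that measure is not specific, and 101 of the 3817 genes called higher had a ratio as high as the lowest marker. Expression by the tumour cells cannot be told apart from carried-in reads, because a cardiac-like programme stronger in 1 tumour would give the same 4.42; TTN is also in the skeletal muscle list.

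Protein-coding genes of chromosome 4 were lower in LASP1-OE as a block, with a median log2 fold change of −0.39 over 480 genes against −0.05 over all (201 lower, 67 higher), and the next lowest chromosome, 19, was at −0.15. After removal of GC trends the difference was −0.38, and among genes changed by at most 1 it was −0.22, which argues against GC content and against a few strongly changed genes. Fewer copies of chromosome 4 in the LASP1-OE cells are a candidate explanation, since all 10 windows along the chromosome had a median below that of all genes, from −0.20 to −0.60. DNA copy number was not analysed here, and a regulatory difference over the chromosome was not tested. REST, HERC5, HERC6, DDX60 and the UGT2B genes lie on this chromosome, as does TLL1, which rose (7.90).

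Androgen-responsive genes, sterol synthesis genes and proliferation genes were lower together. After removal of trends with GC content and transcript length the highest of the 3 list medians was −1.19, which argues against those trends as the whole cause. Weaker androgen signal would raise genes that androgens are known to repress. Of 5 such genes 3 were lower (UGT2B15, UGT2B17 and HSD17B6) and 2 higher (OPRK1 and AKR1C3). The rule set down beforehand took at least 3 lower genes as arguing against weaker androgen signal, and it was met. That rule treated neighbouring genes as separate. The UGT2B pair shares sequence and a chromosome, and by locus, a count outside the rule, 2 were lower and 2 higher. Because of this even split by locus, the test does not decide whether androgen signal was weaker. The over-expression itself and any other difference that goes with the group, in the cells or technical, stay open as untested explanations. With 1 set of cells per label, this design cannot tell them apart. The library names of LASP1-OE also differ in form from those of MOCK.

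Of 8 genes with at least 50 CPM in LASP1-OE and at least 100-fold lower in MOCK, the median level was 0.0744% of the LASP1-OE level in MOCK replicate 1 and 0.855% in MOCK replicate 2, and 8 of 8 were higher in MOCK replicate 2. Of 12 genes chosen in the same way for MOCK, the median level was 0.263% of the MOCK level in LASP1-OE replicate 1 and 0.228% in LASP1-OE replicate 2.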
